A study of Rattus norvegicus with 15 samples.

How the data were processed

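RNA from the nucleus accumbens, a ventral striatal region studied for its part in reward and drug seeking, was measured on Affymetrix rat arrays in 15 samples, 1 array per sample. The deposited table holds log2 expression values that the authors had made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set, so the arrays had been brought to a common scale before deposit. The software that ran it and the filters applied are not given in the sources used here. The labels' protocol names a labelling kit for 3' arrays, while the identifiers are those of a whole-transcript array, and this difference was left open. Scanner files were not used here.

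The table had 28826 probe sets, with 0 missing values and 0 values below 0. The platform annotation paired 15209 probe sets with 1 gene symbol and 306 with several, and 13311 were unnamed here. Of the probe sets with 1 symbol, 15178 were matched by Entrez gene ID to the RefSeq table of assembly GRCr8, which was used only for names. No probe set with several symbols was named. The 14497 genes with 1 symbol were each represented by the probe set with the highest mean over the 15 arrays (494 genes had more than 1). Genes were kept where that probe set lay above the 30th percentile of the array on at least 3 arrays, which left 11778 genes.

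Groups came from the sample labels. One linear model was fitted over all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 5 groups as the only term. It gave 8 comparisons of 2 groups, the effect of withdrawal length averaged over the test, the effect of the extinction test averaged over withdrawal length, their interaction, and a moderated F test over the 5 groups. The residual degrees of freedom were 10 and the prior degrees of freedom 3.44. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Gene lists, 29 in number, were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation, cameraPR and fry were run beside it. For lists described below, member counts were also adjusted over the list alone, with no further adjustment for the number of lists or comparisons. Mean list scores (the mean over members of each member's deviation from its mean over the 15 arrays) were compared between 6 and 6 arrays by exact permutation within strata (400 arrangements, two-sided). With 3 arrays against 3, an exact two-sided test cannot give a p below 0.1.

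The genes named below followed a rule fixed before the data were examined. In each comparison of 2 groups, the rule took up to 10 genes per direction among those past the threshold whose groups did not overlap. Where fewer than 6 passed, it filled up to 6 per direction by smallest unadjusted p among genes whose groups did not overlap, stated not to pass. It also took 3 members of each list past the camera threshold and a fixed set of genes of known interest, and for the averaged effects the 8 smallest p-values in each direction. Members named as past the threshold over the list alone were chosen after their values were seen, where the rule does not take them.

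Before the data were examined, alternatives were fixed for the filter, the choice of probe set, normalization, variance model, array weights, arrays fitted, replicate number as a block and threshold, and for leaving out each array in turn. After the data were seen, the level of cortical neuron markers was added as a covariate. This cortical score is the mean of the 19 measured cortical projection neuron markers that are on no other list. The fit was tested on simulated data for 30C against 30W over 11778 genes, with 200 genes changed. It recovered 86.4% of genes changed by 0.5 on the log2 scale and 98.3% of those changed by 1 log2 unit, with a mean of 10.7 and 11.4 false calls. The simulated genes varied independently of one another, unlike the real ones. With 200 genes changed at once the adjusted threshold is easier to reach than with few, and smaller numbers were not simulated. In the real comparison Nr4a1, with a log2 change of 1.00, had adjusted p = 0.72 in limma. A count of 0 genes therefore does not exclude changes of this size. A further simulation kept the real correlation between genes and held no group effect. In it camera at its preset correlation called a median of 6 of the 29 lists per draw, at most 13, with a call in 100 of 100 draws. With an estimated correlation a list was called in 1 of the 100 draws.

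The labels do not say whether an array holds RNA of 1 rat or of several. P-values then measure only the spread between these samples, and the number of arrays, 3 per group, limits the precision.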

Results

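Gene expression was measured in the nucleus accumbens of rats in a study of the incubation of cocaine craving, the growth of cue-induced drug seeking over weeks of abstinence. There were 15 arrays in 5 groups of 3. One group had received saline (Sal), and its labels also give 10 days of self-administration. The other groups self-administered cocaine for 10 days and then underwent withdrawal of 1 day (1W) or 30 days (30W). Groups 1C and 30C had the same withdrawal and also an extinction test, in which cocaine seeking in response to cues was assessed. The labels do not give a withdrawal time or a test for the saline rats. The values are RMA log2 intensities, and the correlation between any pair of arrays lay between 0.9929 and 0.9967.

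The arrays differed in the level of cortical neuron markers within groups. Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 7.16 in Sal replicate 1 to 12.16 in 30C replicate 1, a 31.9-fold range. The cortical score ranged from -0.84 in Sal replicate 1 to 0.72 in 30C replicate 1, and was 0.53 in Sal replicate 3 and -0.47 in 30C replicate 3. The first principal component of the arrays, with 27.9% of the variance, correlated with this score (Pearson r = 0.97, Spearman rho = 0.95). The score of medium spiny neuron markers, the principal neurons of the striatum, was lowest in 30C replicate 1 at -0.38. The arrays also differed in the 25th percentile of their values, which lay between 5.48 and 5.51 on the 6 day 1 arrays and between 5.53 and 5.59 on the 6 day 30 arrays. The exact permutation p was 0.0022 (two-sided, 6 against 6), the smallest that 924 splits can give. Sal arrays lay between 5.51 and 5.57.

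**Figure D1:**
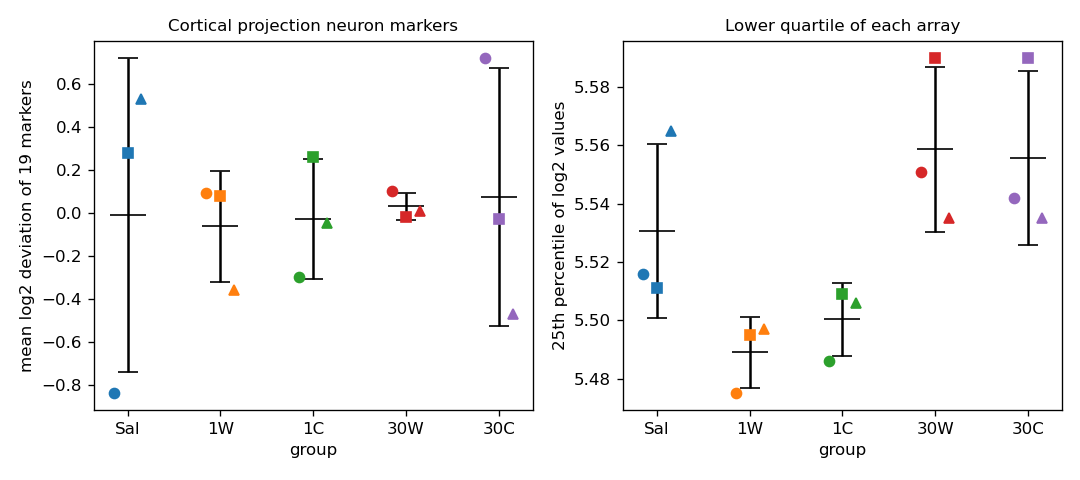
Cortical marker score (left, mean log2 deviation of 19 markers) and 25th percentile of log2 values (right) for each of the 15 arrays by group; symbols are replicates 1 (circle), 2 (square) and 3 (triangle), bars are mean and SD. Cortical scores spread from -0.84 to 0.72, and the 25th percentile is higher on every day 30 array than on every day 1 array.

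The comparison of 30C with 30W asks how expression differed after the extinction test at 30 days. Of 47 immediate early genes, which neurons transcribe within minutes of activity, 12 rose, 0 fell and 35 did not pass when adjusted over the list alone, and 0 passed over all 11778 genes in limma. Camera gave the list adjusted p = 1.6e-25, and adjusted p = 0.31 with an estimated correlation. Nr4a1 and Nr4a3, orphan nuclear receptors induced by activity, had log2 changes of 1.00 (SE 0.24) and 1.01 (SE 0.23), and the transcription factor gene Egr2 one of 0.83 (SE 0.18). Nfil3, a basic leucine zipper repressor, went from 7.41 ± 0.02 (SD, n = 3) in 30W to 7.96 ± 0.16 (SD, n = 3) in 30C. Fosl2, Junb and Fos, components of AP-1, differed by 0.58 (SE 0.11), 0.59 (SE 0.15) and 0.49 (SE 0.15), and the kinase gene Sik1 by 0.44 (SE 0.08).

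Besides those named above, Egr4, Per1, Klf2 and Dusp4 rose by the list-alone count. With the cortical score as a covariate, chosen after seeing the data, 20 members passed over the list alone, and the list gave adjusted p = 0.026 with an estimated correlation. Without 30C replicate 1, the array with the highest cortical score, 10 members passed.

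**Figure D2:**
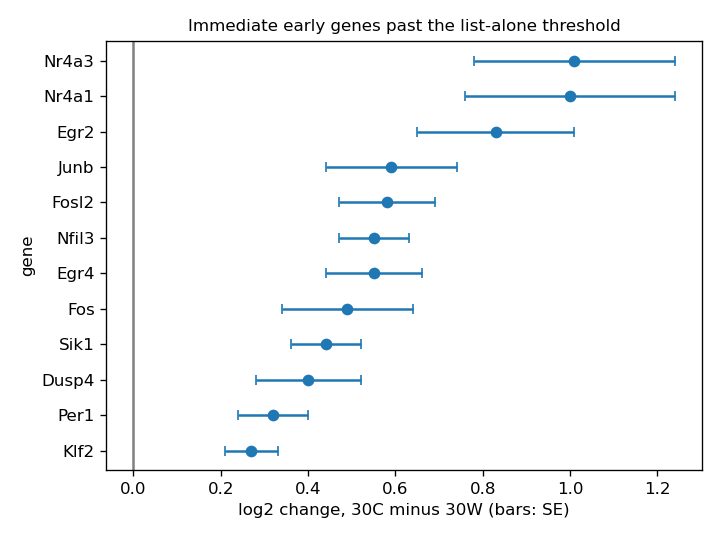
Log2 change of immediate early genes in 30C relative to 30W (horizontal axis) for the 12 genes past the threshold adjusted over the list alone; points are limma estimates from 3 arrays per group and bars their SE. Changes run from 0.27 for Klf2 to 1.01 for Nr4a3.

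Outside that list, Ifit2, an interferon-induced gene, fell by 0.35 (SE 0.09) and the clock gene Nr1d2 by 0.19 (SE 0.05), each adjusted over its own list alone and not over all genes. Ifit2 was at 6.94, 6.72 and 7.01 on the 30W arrays and 6.53, 6.51 and 6.59 on the 30C arrays. Sal arrays lay between 6.52 and 6.7, so 30W rather than 30C stood apart from Sal. The score of its list was 0.21 and 0.20 on 30W replicates 1 and 3 and -0.11 on replicate 2. Medium spiny neuron markers were negative in 30 of 35 members, oligodendrocyte markers in 27 of 29 and endothelial and mural cell markers in 21 of 25, each with adjusted p = 0.91 with an estimated correlation. The medium spiny neuron score was -0.38, 0.06 and 0.11 on the 30C arrays and 0.04, -0.05 and 0.07 on the 30W arrays. Its lower mean in 30C therefore came from 30C replicate 1. The genes named next did not pass. Csrp2, encoding a LIM domain protein, had a log2 change of -0.36 (SE 0.07) and Kng1 one of -0.74 (SE 0.16), and Csrp2 passed only without Sal replicate 3 (adjusted p = 0.035). Arc was at 0.60 (SE 0.26), Egr1 at 0.42 (SE 0.15) and Bdnf at 0.14 (SE 0.15). The dopamine receptor genes Drd1 and Drd2 were at -0.20 (SE 0.17) and -0.06 (SE 0.15), and the glutamate receptor genes Gria1 and Gria2 at -0.02 (SE 0.06) and -0.03 (SE 0.05). In limma 0 genes passed over all genes, with 463 at an unadjusted p under 0.05, where 589 would be the chance number. Nfil3 had the smallest adjusted p, 0.0761. With the cortical score as a covariate Nfil3 passed (adjusted p = 0.0062), the 1 gene that did. It passed also with array weights (adjusted p = 0.034) and without 1C replicate 2 (adjusted p = 0.036).

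The comparison of 30C with Sal sets the tested day 30 rats against the saline rats. Of the 47 immediate early genes 21 rose, 0 fell and 26 did not pass, adjusted over the list alone, against 0 over all genes. Camera gave adjusted p = 1.31e-31 for the list, and adjusted p = 0.17 with an estimated correlation. Klf2, a Krüppel-like factor, differed by 0.39 (SE 0.06), Nfil3 by 0.42 (SE 0.08), Fosl2 by 0.55 (SE 0.11), and Egr4 by 0.52 (SE 0.11). Over the list alone 5 members passed without 30C replicate 1, 7 without Sal replicate 1 and 11 without Sal replicate 2. With the cortical score as a covariate 29 passed, and the list gave adjusted p = 0.014 with an estimated correlation.

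Of 26 glucocorticoid-responsive genes 4 rose in 30C against Sal, adjusted over the list alone, against 0 over all genes, and the list gave adjusted p = 0.57 with an estimated correlation. These were Cdkn1a at 0.72 (SE 0.16), Sgk1 at 0.46 (SE 0.14), Pdk4 at 0.64 (SE 0.20) and Ddit4 at 0.21 (SE 0.06). Heat shock genes were positive in 31 of 31 members (camera adjusted p = 2.55e-07, and adjusted p = 0.57 with an estimated correlation), with Hspb1 alone past the threshold over the list alone. Oligodendrocyte markers were negative in 27 of 29 members (camera adjusted p = 6.95e-07, and adjusted p = 0.82 with an estimated correlation), and among them Fa2h fell by 0.26 (SE 0.07), adjusted over the list alone. The clock gene Nr1d2, which encodes a REV-ERB repressor, fell by 0.22 on the log2 scale (adjusted over the list alone). Over all genes limma passed 0, with 596 at an unadjusted p under 0.05. The smallest adjusted p was 0.218, for Klf2.

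The comparison of 30C with 1C asks whether expression after the test differed between withdrawal times. Nfil3 was higher in 30C by 0.51 (SE 0.08), Nr4a1 by 0.78 (SE 0.24), Egr2 by 0.53 (SE 0.18) and Gadd45g by 0.29 (SE 0.08). Of the 47 immediate early genes 12 rose and 35 did not pass, adjusted over the list alone, against 0 over all genes. Camera gave adjusted p = 1.39e-19 for the list, and adjusted p = 0.40 with an estimated correlation. All of the 12 except Nfil3 had an adjusted p of 0.046 over the list alone, at the edge of the threshold. The count was 1 after a further quantile normalization, after median centring, with a trended and robust variance and with replicate number as a block. It was also 1 without Sal replicate 2, 1W replicate 3, 30W replicate 1, 1C replicate 1, 1C replicate 3 or 30C replicate 1, 2 without 30C replicate 2, and 6 without 30W replicate 3 or 30C replicate 3. The clock genes Nr1d1 and Nr1d2 fell by 0.29 and 0.22 on the log2 scale, adjusted over the list alone. Markers of several cell types were mostly negative, microglia and macrophage in 28 of 29 members, endothelial and mural in 23 of 25, blood in 6 of 6 and medium spiny neuron in 33 of 35. Camera called each (adjusted p = 9.55e-06, 5.99e-06, 0.000266 and 0.00835), with adjusted p = 0.40, 0.56, 0.40 and 0.80 with an estimated correlation. The microglia score was 0.19 on 1C replicate 2 against -0.01 and 0.01 on the other 1C arrays, and the medium spiny neuron score was -0.38 on 30C replicate 1 against 0.06 and 0.11 on the other 30C arrays. Among these members Alas2 alone passed adjusted over its list, falling by 0.46 (SE 0.12). Lgals3, a galectin of activated microglia and macrophages, was at -0.34 (SE 0.07) and did not pass, but passed without 30C replicate 3 (adjusted p = 0.031). In limma 0 genes passed over all genes, with 646 at an unadjusted p under 0.05. With the cortical score as a covariate 1 gene passed, Nfil3 (adjusted p = 0.016), which passed also with array weights (adjusted p = 0.049) and without 1C replicate 2 (adjusted p = 0.029).

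The comparison of 1C with 1W asks how expression differed after the test at 1 day. Of 29 markers of oligodendrocytes, which form myelin, 7 fell, 0 rose and 22 did not pass, adjusted over the list alone, and 0 passed over all genes. Camera gave adjusted p = 1.93e-21, and adjusted p = 0.42 with an estimated correlation. Gjb1, a gap junction gene of myelin, was at -0.30 (SE 0.07), Fa2h, which makes myelin lipids, at -0.26 (SE 0.07), Qdpr at -0.34 (SE 0.10) and Opalin at -0.30 (SE 0.10). The list score was 0.23, 0.18 and -0.04 on the 1W arrays and -0.03, -0.07 and -0.07 on the 1C arrays. The count was 0 with only the arrays compared, 15 with a trended and robust variance, 17 after median centring or with replicate number as a block, 19 with array weights, 20 at an adjusted p under 0.10 and 4 at 1.2-fold or more. It was 0 without 1W replicate 1, 1W replicate 2, 1C replicate 2 or 1C replicate 3, 23 without 1W replicate 3, and between 2 and 14 without Sal replicates 1 or 3, 30W replicates 1 or 3, or 30C replicates 2 or 3. Choroid plexus and ependymal markers were positive in 12 of 14 members (camera adjusted p = 0.000129, and adjusted p = 0.42 with an estimated correlation), with 0 past the threshold over the list alone. Their score was 0.34 on 1C replicate 1 and -0.01 and -0.02 on the other 1C arrays.

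Of the immediate early genes 0 of 47 passed at 1 day adjusted over the list alone, with a median log2 change of 0.09. Camera gave adjusted p = 5.98e-06, and adjusted p = 0.66 with an estimated correlation. The interaction, which tests the difference from 30 days, gave the list adjusted p = 1.73e-06 by camera, and adjusted p = 0.90 with an estimated correlation. Lgals3 was at 0.42 (SE 0.07), Aurkb at 0.73 (SE 0.16) and Sfrp1, a secreted Wnt antagonist, at 0.63 (SE 0.16), and none of these passed. Lgals3 passed without 30C replicate 3 (adjusted p = 0.032). Among all genes 0 passed in limma, with 474 at an unadjusted p under 0.05.

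**Figure D3:**
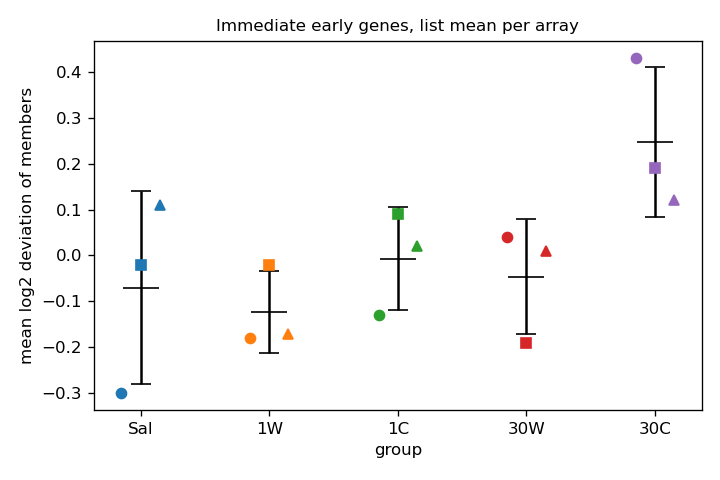
Mean log2 deviation of the 47 immediate early genes from their mean over the 15 arrays, per array and group; symbols are replicates 1 (circle), 2 (square) and 3 (triangle), bars are mean and SD (n = 3). The 30C arrays are at 0.43, 0.19 and 0.12.

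The comparison of 30W with 1W follows withdrawal without a test. Of 29 microglia and macrophage markers 6 fell, 0 rose and 23 did not pass, adjusted over the list alone, against 0 over all genes. Camera gave adjusted p = 0.000123, and adjusted p = 0.78 with an estimated correlation. Cx3cr1, the fractalkine receptor, fell from 10.50 ± 0.05 (SD, n = 3) to 10.22 ± 0.04 (SD, n = 3), and Gpr34 was at -0.36 (SE 0.08), P2ry13 at -0.28 (SE 0.08) and Csf1r at -0.20 (SE 0.06). Markers of other cell types went both ways. Oligodendrocyte markers were negative in 28 of 29 members (camera adjusted p = 9.28e-06), with Fa2h at -0.29 (SE 0.07) and Ugt8 at -0.32 (SE 0.09) past the threshold adjusted over the list alone, and endothelial and mural cell markers in 25 of 25 (camera adjusted p = 0.000865). Both lists had adjusted p = 0.78 with an estimated correlation. Choroid plexus and ependymal markers were positive in 12 of 14 (camera adjusted p = 0.00551, and adjusted p = 0.78 with an estimated correlation), with a mean log2 change of 0.19. Their score was 0.33 on 30W replicate 3 and -0.07 and -0.06 on the other 30W arrays. Cortical markers, positive in 15 of 20, were not called by camera (adjusted p = 0.144). Of 6 blood cell markers Alas2 and Hbb fell by 0.36 and 0.47 and Epb42 rose by 0.32, adjusted over the list alone. The 25th percentile of the arrays separated the same groups. The microglia count was 2 with only the arrays compared and 3 after a further quantile normalization or at 1.2-fold or more. It was 2 without 30W replicate 2 or 30W replicate 3, and 3 without Sal replicates 1 or 2, 1W replicates 1 or 3, 30W replicate 1 or 1C replicate 1.

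Of 14 markers of oligodendrocyte precursors 3 fell, adjusted over the list alone, against 0 over all genes, and the list gave adjusted p = 0.78 with an estimated correlation. These were Vcan at -0.23 (SE 0.06), Sox6 at -0.23 (SE 0.08) and Gpr17 at -0.25 (SE 0.09). Bst2, an interferon-induced gene, rose by 0.33 (SE 0.06), the 1 gene of 32 in the inflammatory and interferon list that passed adjusted over the list alone. That list gave adjusted p = 0.78 with an estimated correlation. Bst2 went from 5.67 to 6.00, near the lower end of the range. There the 208 olfactory receptor genes (median level 6.09) had a median log2 change of 0.08 in this comparison. Of these, 23 were higher and 1 lower at an unadjusted p under 0.05 in limma. Cd180, a Toll-like receptor homologue of immune cells, was at -0.51 (SE 0.08) and Dapp1 at -0.38 (SE 0.06), and neither passed. Cd180 passed with array weights (adjusted p = 0.049) and without 30W replicate 1 (adjusted p = 0.012). Over all genes limma passed 0, with 1188 at an unadjusted p under 0.05, and 3 passed with array weights (Cd180, Spata32 and RT1-CE13).

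The comparisons of 1W and 1C with Sal set rats 1 day after cocaine against saline rats. In each, 4 of 6 blood cell markers rose, adjusted over the list alone, against 0 over all genes. The list gave adjusted p = 0.46 with an estimated correlation in 1W and adjusted p = 0.36 with an estimated correlation in 1C. The haemoglobin gene Hbb was at 0.45 (SE 0.15) in 1W and 0.52 (SE 0.15) in 1C, and Alas2, of haem synthesis, at 0.42 (SE 0.12) and 0.45 (SE 0.12). Endothelial and mural cell markers were positive in 25 of 25 members in 1W (camera adjusted p = 7.49e-09, and adjusted p = 0.46 with an estimated correlation) and in 21 of 25 in 1C (0.000179, and adjusted p = 0.65 with an estimated correlation). Of these only Esam in 1C, at 0.34 (SE 0.08), passed adjusted over the list alone. Oligodendrocyte markers went opposite ways, positive in 27 of 29 members in 1W (camera adjusted p = 1.99e-06, and adjusted p = 0.97 with an estimated correlation) and negative in 28 of 29 in 1C (1.53e-06, and adjusted p = 0.65 with an estimated correlation). In 1C meningeal and fibroblast markers were positive in 18 of 19 members (camera adjusted p = 2.23e-05) and choroid plexus and ependymal markers in 12 of 14 (0.00397), both with adjusted p = 0.48 with an estimated correlation. Of these 3 lists 0 members passed over the list alone. On 1C replicates 1, 2 and 3 the choroid plexus score was 0.34, -0.01 and -0.02, and the meningeal score 0.27, 0.1 and -0.07. Microglia and macrophage markers were positive in 26 of 29 and 22 of 29 members, with 0 past the threshold over the list alone, and adjusted p = 0.46 and 0.48 with an estimated correlation. The microglia score was 0.19 on 1C replicate 2 and -0.01 and 0.01 on the other 1C arrays. The same array had the highest inflammatory score, 0.50, with the chemokine genes Ccl2 at 9.75 and Cxcl10 at 9.28. The 1W blood count was 0 without Sal replicate 1 or 1W replicate 3, 2 without Sal replicate 3 or 1W replicate 2, 1 without the filter on low values and 2 with array weights. The 1C count was 2 without 1C replicate 1.

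Olfactory receptor genes, which lie near the lower end of the range (median level 6.09, against 8.18 for all genes), had a median log2 change of -0.16 in 1W and -0.12 in 1C relative to Sal. The 25th percentile was also lower on day 1 arrays. In 1W, Or2ak4c was at -0.39 (SE 0.06) and Or8c19 at -0.57 (SE 0.10), and Tal1 at 0.31 (SE 0.06) and Plvap, of fenestrated endothelium, at 0.27 (SE 0.05). In 1C, Lgals3 was at 0.44 (SE 0.07) and P2ry6 at 0.25 (SE 0.06). None of these passed, except Lgals3 without 30C replicate 3 (adjusted p = 0.019). In limma 0 genes passed in each comparison, with 573 (1W) and 404 (1C) at an unadjusted p under 0.05.

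The comparison of 30W with Sal found Bst2 at 0.25 (SE 0.06) and Psmb8, an immunoproteasome subunit, at 0.26 (SE 0.06). These 2 of 32 inflammatory and interferon-responsive genes rose, adjusted over the list alone, against 0 over all genes. The list gave adjusted p = 0.99 with an estimated correlation. Its score was 0.21 and 0.20 on 30W replicates 1 and 3, but -0.11 on 30W replicate 2. Dnaja4, a heat shock protein gene, was at 0.33 (SE 0.06), Tal1 at 0.34 (SE 0.06) and Sult1c2 at -0.81 (SE 0.18), and these did not pass. Among all genes 0 passed in limma, with 895 at an unadjusted p under 0.05, and 2 probe sets passed when all were tested one by one.

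Averaged over the test, Cd180 fell by 0.41 (SE 0.05) on the log2 scale at 30 days relative to 1 day, the 1 gene that passed in limma (adjusted p = 0.0288), with 1531 genes at an unadjusted p under 0.05. It was not called when the 12 cocaine arrays were fitted alone, nor without Sal replicate 2, 1W replicates 1 or 2, 30W replicates 2 or 3, 1C replicates 1 or 3, or 30C replicates 2 or 3. Dapp1 at -0.30 (SE 0.04), Evx1 at 0.26 (SE 0.04) and Itga10 at 0.27 (SE 0.04) did not pass, though all 3 passed with array weights (adjusted p = 0.029, 0.029 and 0.015). Evx1 (group means 6.38 to 6.67) and Itga10 (6.28 to 6.6) lay near the lower end of the range. The 208 olfactory receptor genes, also low, had a median log2 change of 0.08 here. Of these, 39 were higher and 0 lower at an unadjusted p under 0.05 in limma. Of 29 microglia and macrophage markers 6 fell, and of 6 blood cell markers 5 fell, adjusted over each list alone. Camera gave these lists adjusted p = 0.58 with an estimated correlation. The microglia count was 10 after a further quantile normalization or at an adjusted p under 0.10, 14 after median centring, 0 at 1.2-fold or more and 12 without 1W replicate 3. The blood count was 3 at 1.2-fold or more, 2 without 1W replicate 3 or 30W replicate 2 and 3 without 1W replicate 2. The exact permutation p of the mean list score (400 arrangements, two-sided) was 0.005 for microglia and for oligodendrocyte precursors, 0.01 for blood and 0.02 for endothelial and mural cells, or 0.0725, 0.0725, 0.0967 and 0.145 adjusted over the 29 lists. The unadjusted 0.005 is the smallest p that 400 arrangements can give. A list at this floor passes the adjustment over 29 lists only if several lists reach it. Of the oligodendrocyte precursor markers 2 of 14 fell and of the endothelial and mural markers 2 of 25, adjusted over each list alone, with adjusted p = 0.59 and 0.58 with an estimated correlation. Of the immediate early genes 4 of 47 rose, adjusted over the list alone (adjusted p = 0.58 with an estimated correlation, and 0.186 by permutation over the 29 lists).

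**Figure D4:**
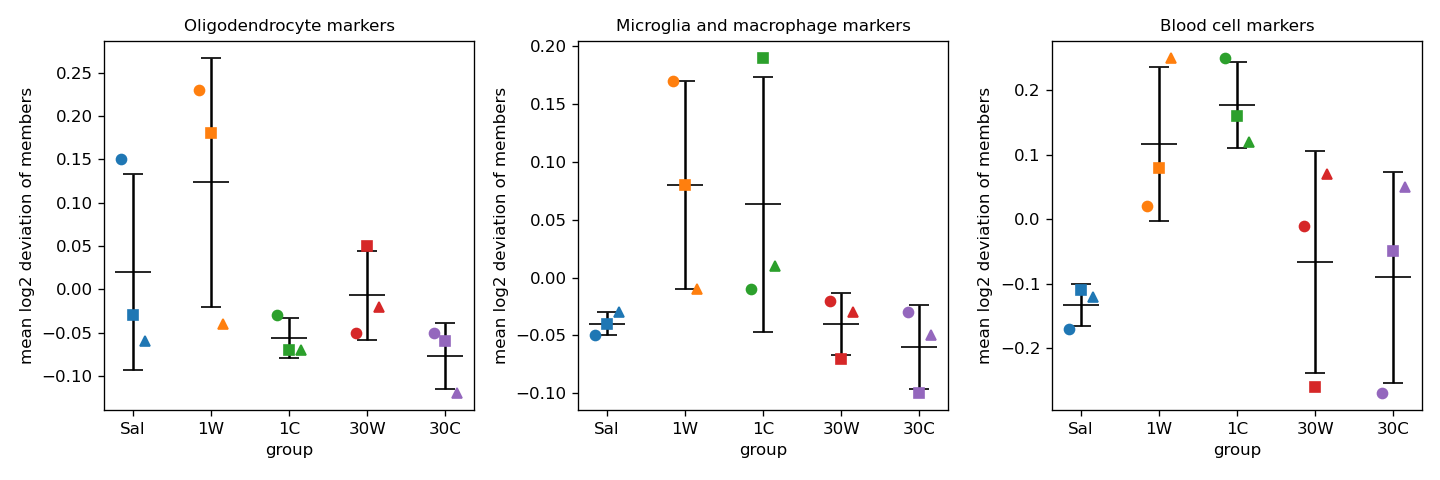
Mean log2 deviation of oligodendrocyte, microglia and macrophage, and blood cell markers per array and group; symbols are replicates 1 (circle), 2 (square) and 3 (triangle), bars are mean and SD (n = 3). The oligodendrocyte score is 0.23 and 0.18 on 1W replicates 1 and 2 and lies at or below 0.15 on the other arrays.

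Averaged over withdrawal length, 13 of 47 immediate early genes rose and 14 of 29 oligodendrocyte markers fell with the test, adjusted over each list alone, against 0 over all genes. Camera gave adjusted p = 0.37 with an estimated correlation for the former and adjusted p = 0.48 with an estimated correlation for the latter. The oligodendrocyte count was 0 at 1.2-fold or more, 0 without 1W replicates 1 or 2, 30W replicate 2, 1C replicates 2 or 3, or 30C replicate 3, and 2, 9 and 8 without 30W replicate 3, 30C replicate 1 and 30C replicate 2. The exact permutation p of the list score was 0.02 for each (400 arrangements, two-sided), or 0.29 adjusted over the 29 lists. Nfil3 was at 0.33 (SE 0.05), Sik1 at 0.31 (SE 0.05) and Tmem88b at -0.24 (SE 0.04). Over all genes limma passed 0, with 571 at an unadjusted p under 0.05. With the cortical score as a covariate Nfil3 and Nr4a3 passed (adjusted p = 0.04 for Nfil3).

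The interaction asks whether the response to the test differed between 1 and 30 days. In limma 0 genes passed, with 357 at an unadjusted p under 0.05, and 0 under each alternative tried. Nfil3 had an interaction of 0.45 (SE 0.11) and Lgals3 one of -0.45 (SE 0.10), and neither passed over all genes. Over the circadian clock list alone Nfil3 passed (adjusted p = 0.02 in limma). Of the 47 immediate early genes 0 passed adjusted over the list alone. The moderated F test over the 5 groups found 0 genes, with 820 at an unadjusted p under 0.05.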

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

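The tests in this part that weigh explanations were chosen after the results were seen; the counts over other splits of the arrays were planned before those counts were seen. In 6 gene lists the response to the test differed between 30 days and 1 day by camera at its preset correlation, a test of the interaction itself. The median log2 difference in response was 0.15 for immediate early genes, -0.11 for medium spiny neuron markers, 0.09 for oligodendrocyte markers, -0.17 for choroid plexus and ependymal markers, -0.10 for meningeal and fibroblast markers and -0.24 for inflammatory and interferon-responsive genes. With an estimated correlation each of these had an adjusted p of 0.90 or above, and in data simulated without effects the preset correlation called a median of 6 lists. The inflammatory score was 0.50 on 1C replicate 2 and -0.06 and -0.08 on the other 1C arrays. It was 0.21, -0.11 and 0.20 on 30W replicates 1, 2 and 3, and -0.07, -0.06 and -0.03 on the 30C arrays. The choroid plexus score was 0.34 on 1C replicate 1, 0.33 on 30W replicate 3 and 0.30 on 30C replicate 3, and at or below 0.05 on the others. The meningeal score was 0.27 on 1C replicate 1 and at or below 0.16 on the others.

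Of 47 immediate early genes 12 rose and 35 did not pass in 30C against 30W, adjusted over the list alone, and the list had adjusted p = 0.31 with an estimated correlation. A greater share of cortical tissue in the 30C samples is argued against as the whole cause, since the difference of the list mean was 0.29 without and 0.28 with the cortical score as a covariate (95% interval 0.15 to 0.41). The array 30C replicate 1 alone is also argued against for 30C against 30W, since 10 members passed over the list alone without it and 12 with it. The list score was 0.43, 0.19 and 0.12 on the 30C arrays and 0.04, -0.19 and 0.01 on the 30W arrays. On Sal replicate 3 it was 0.11. Against Sal the count fell from 21 to 5 without that array. Against 1C it fell from 12 to 1, as it did without several other arrays. Activity induced by the test at 30 days, or by handling that went with it, may account for the difference and stays open, since no group here separates these. The time of day at which tissue was taken is not given in the sources used here. Nfil3 and Per1 are also clock genes, so a difference in that time was not excluded.

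Of 29 oligodendrocyte markers 7 fell and 22 did not pass in 1C against 1W, adjusted over the list alone, and the list had adjusted p = 0.42 with an estimated correlation. A smaller share of white matter in the 1C samples may account for this and stays open. Members moved together between arrays of the same group, with a mean correlation of 0.65. That value belongs to the list over all groups and is the same in every comparison, and medium spiny neuron markers had 0.72. It therefore cannot decide the question for 1C against 1W. The share of cortical tissue is argued against, since the difference of the list mean was -0.18 without and -0.18 with the cortical score (95% interval -0.35 to -0.01). Members were also negative without a test, in 30W against 1W (28 of 29), and with one in 30C against 30W (27 of 29), 1C against Sal (28 of 29) and 30C against Sal (27 of 29), and positive in 1W against Sal (27 of 29), with scores of 0.23 and 0.18 on 1W replicates 1 and 2 but -0.04 on 1W replicate 3. An effect of the test stays open.

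Of 29 microglia and macrophage markers 6 fell and 23 did not pass at 30 days against 1 day, adjusted over the list alone, and the list had adjusted p = 0.58 with an estimated correlation and an exact permutation p of 0.0725 adjusted over the 29 lists. Blood left in the tissue is argued against as the whole cause, since the difference was -0.12 without and -0.15 with the blood marker score as a covariate (95% interval -0.28 to -0.03). A narrower range of values on some arrays is not decided. The median change lay at percentile 0 of 10000 random lists matched on mean level, below that of genes of like level. Those lists were drawn gene by gene and lack the correlation between microglia markers (0.17). Their medians therefore spread less, and the test cannot exclude this cause. A difference between array batches that followed withdrawal length cannot be told apart from withdrawal itself, because the 25th percentile separated all 6 day 30 arrays from all 6 day 1 arrays. Withdrawal length as such stays open as well. So does any trait of the rats that went with it, such as age, which was not among the variables used here.

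With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In the gene counts, with 0 genes in each real comparison and therefore 10 of 10 splits at least as high, the highest other split gave 0 genes for 1W against Sal, 30W against 1W and 30C against 1C, and 1 gene for 30W against Sal, 1C against Sal, 1C against 1W and 30C against 30W. For 30C against Sal another split gave 231 genes, which points to a structure of the samples other than their groups. It set Sal replicate 1, 30C replicate 2 and 30C replicate 3 (cortical scores -0.84, -0.03 and -0.47) against Sal replicates 2 and 3 and 30C replicate 1 (0.28, 0.53 and 0.72). This split therefore followed the cortical score, with which the first principal component (27.9% of variance) correlated at Pearson r = 0.97. In the list counts, the real value and the highest other split were 6 and 14 lists for 1W against Sal, 2 and 13 for 30W against Sal, 13 and 15 for 1C against Sal, 5 and 13 for 30C against Sal, 9 and 13 for 30W against 1W, 6 and 15 for 30C against 1C, 9 and 13 for 1C against 1W, and 9 and 13 for 30C against 30W. In the order just given, 8, 8, 5, 9, 4, 10, 7 and 3 of the 10 splits called as many lists. For the member counts adjusted over the list alone only 1 of 10 splits, the real one, reached its value. These lists and comparisons were picked after their real counts were seen, which favours the real split. Its first rank is therefore no independent support. The real value and the highest other were 21 and 0 for immediate early genes in 30C against Sal, 12 and 0 in 30C against 1C and 12 and 0 in 30C against 30W. They were 7 and 3 for oligodendrocyte markers in 1C against 1W, 6 and 0 for microglia markers in 30W against 1W, and 4 and 1 (1W) or 4 and 0 (1C) for blood markers against Sal.

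For the averaged effects, 100 regroupings of the 12 cocaine arrays were drawn, and for the F test 100 of all 15 arrays. For the 1 gene of withdrawal length chance could not be excluded (5 of 100 regroupings gave as many, the highest other 2). The counts of 0 genes decide nothing, since any regrouping gives at least 0 (100 of 100 each, highest other 3 for the test, 2 for the interaction and 21 for the F test). For the list counts chance could not be excluded, with 8 for withdrawal length (59 of 100 gave as many, highest other 17), 8 for the test (53 of 100, highest other 17) and 6 for the interaction (74 of 100, highest other 15). The list-alone counts of the test were 13 immediate early genes (3 of 100 gave as many, highest other 19) and 14 oligodendrocyte markers (1 of 100, highest other 10). Those of withdrawal length were 6 microglia markers (2 of 100, highest other 7) and 5 blood markers (2 of 100, highest other 5). These lists were picked from 29 after their counts were seen, and the shares are not adjusted for that. Adjusted over the 29 lists, the exact permutation p of the list score was 0.29 for immediate early genes and for oligodendrocyte markers, 0.0725 for microglia and 0.0967 for blood, so chance is not excluded for any of them. For microglia the unadjusted permutation p of 0.005 was the smallest that 400 arrangements can give. Missing the adjusted threshold therefore does not decide the question for that list.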

How the results depend on the processing

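Most settings were fixed before the data were examined; the cortical score as a covariate and fry were chosen after seeing the data. Gene counts over all genes were 0 in every comparison of 2 groups, in both directions, and moved by few genes, while the list-alone counts moved more, and the cause of these changes was not tested unless stated. For withdrawal length averaged over the test, the 1 gene became 2 with the 50th percentile filter, 3 for all probe sets one by one, 4 after quantile normalization again, 2 after median centring, 6 with array weights, 5 at an adjusted p under 0.10 and 0 with only the arrays compared. Counts of 0 became 2 (30W against Sal) and 1 (F test) for all probe sets, 3 (30W against 1W), 2 (30C against 1C) and 1 (30C against 30W) with array weights, and 1 (30C against 30W) at an adjusted p under 0.10. With the cortical score they became 1 (30C against 1C, 30C against 30W and the F test) and 2 (the averaged test). Leaving out 1 array at a time gave 0 to 1 genes for 1C against Sal, 30W against 1W, 1C against 1W and 30C against 30W, 0 to 2 for 30C against 1C and the F test, 0 to 3 for withdrawal length, and 0 for each other comparison. Of the list-alone counts, immediate early genes in 30C against 30W held between 10 and 16 with 1 array left out and rose from 12 to 20 with the cortical score. The ranges with 1 array left out were 5 to 26 in 30C against Sal, 1 to 15 in 30C against 1C and 11 to 16 for the averaged test. The 12 in 30C against 1C became 1 after quantile normalization, median centring, a trended robust variance or the replicate block. Oligodendrocyte markers in 1C against 1W, 7 by the main setting, gave 17 with median centring, 15 with a trended robust variance, 19 with array weights, 17 with the replicate block, 20 at an adjusted p under 0.10, 4 at 1.2-fold or more and 0 with only the arrays compared, and 0 to 23 with 1 array left out. For the averaged test they gave 0 at 1.2-fold or more and 0 to 21 with 1 array left out. Microglia markers in 30W against 1W gave 3 after quantile normalization, 3 at 1.2-fold or more, 2 with only the arrays compared and 2 to 7 with 1 array left out. For withdrawal length they gave 10 after quantile normalization, 14 with median centring, 10 at an adjusted p under 0.10, 0 at 1.2-fold or more and 4 to 12 with 1 array left out. Blood markers in 1W against Sal gave 1 without the filter, 2 with array weights and 0 to 5 with 1 array left out, 2 to 4 in 1C against Sal, and for withdrawal length 3 at 1.2-fold or more and 2 to 5 with 1 array left out. The 59 list calls over the 8 comparisons of 2 groups became 0 with an estimated correlation, 0 with fry, 2 with the cortical score and an estimated correlation, 61 with the replicate block and 49 to 81 with 1 array left out. Replicate numbers did not pair the arrays throughout. Deviations of same-numbered arrays correlated between -0.63 and 0.51 (median -0.01), with 10 of 30 pairs over 0.1. Of 15 arrays, 6 correlated best with an array of their own number. On the second principal component (14.5% of variance), however, replicate 1 of Sal, 1W, 1C and 30C lay at -6.9, -11, -6.2 and -5.3. Replicate 1 of 30W lay at 5.5 and every other array at 0.1 or above. A structure shared by some arrays numbered 1 is therefore not excluded. Of 419 log2 changes of named genes, 362 kept their sign under all alternatives run, and 57 changed sign, none of them called.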

Other observations

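Of 17 circadian clock genes, 3 passed adjusted over the clock list alone in 30C against 30W, and 0 over all genes. Camera gave the list adjusted p = 0.72, and adjusted p = 0.91 with an estimated correlation. Per1, a light- and activity-induced clock gene, was at 0.32 (SE 0.08), Nfil3 at 0.55 (SE 0.08) and Nr1d2 at -0.19 (SE 0.05). Per1 and Nfil3 are also on the list of immediate early genes. The time of day at which tissue was taken is not given in the sources used here.

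Of 20 genes of DNA methylation and demethylation, 4 passed adjusted over the list alone in 30C against 1C, and 0 over all genes. Camera gave the list adjusted p = 0.987, and adjusted p = 0.99 with an estimated correlation. Gadd45b and Gadd45g, stress-induced genes that are on the immediate early list too, were higher by 0.23 (SE 0.07) and 0.29 (SE 0.08). Apobec1, a cytidine deaminase, was at -0.25 (SE 0.05) and Ahcy, which hydrolyses S-adenosylhomocysteine, at -0.18 (SE 0.05). The methyltransferase genes Dnmt3a and Dnmt1 were at 0.02 (SE 0.06) and 0.05 (SE 0.04) in 30C against 30W and did not pass.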
